A study of Drosophila melanogaster with 4 samples.

How the data were processed

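Binding of GFP-tagged Usp was measured by ChIP-seq in wandering larvae of the third instar, with 2 ChIP and 2 input libraries. Per the labels' protocols, flies were raised at 25 °C and larvae were cross-linked for 15 min in 1.8% formaldehyde. The protocol text names *y; bw cn sp* flies, while the strain label is the Usp-GFP line with the transgene at VK00033. Sex is labelled unknown. Whether the replicates came from separate cultures is not given in the sources used here.

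The authors deposited 1 list of peaks with a score for each, called with MACS per the file headers, on FlyBase release 5. The submitters' processing notes also name BDGP5, BWA, CASAVA 1.7.0.2 and 1.7.0.3, and MACS2, with no role or order. The calling threshold, the filters, the treatment of duplicate and multiply mapped reads, and whether replicates were pooled before calling are not given in the sources used here. What the deposited score measures is not stated either. The list holds no summit, pileup or value per library, so each peak's score is the authors' own value. It was used to describe, rank and filter peaks within the list, to infer pileups and folds, and in tests across peaks.

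The scale of the score was worked out from its values, after the data were seen. Scores shared by at least 10 peaks were compared with −log10 of the Poisson probability of k or more fragments, k a whole number, and the background was chosen to minimise the mean distance. A peak within 0.01 of the series was taken to have been scored against that genome-wide background. Its pileup is then k, and its fold is k over the background. A peak off the series may have been scored against another background, which MACS takes from the surroundings when it is higher, or may have missed the series by the tolerance alone, as 2 common score values did, so no fold is given for it. A tolerance of 0.015, which takes those values in, was tried after the results were seen. The number of reads per library does not follow from the background, since the fragment length is unknown. Intervals of folds (exact Poisson) and shares (exact binomial) are at 95% and cover counting error only.

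Arm densities were tested by a two-sided exact binomial test with Benjamini-Hochberg adjustment over 6 arms. Arm length was the span from first to last peak, since no release 5 genome was used. Clustering was tested against 1000 random placements of the peaks, without overlap, on the span of the same arm, as the share with another peak within 5 kb, edge to edge. Medians were compared and correlations tested by permutation with 100000 resamples, or 10000 for the scores of neighbouring peaks. Windows of 100 kb counted peak midpoints. The 10 highest scores, the 3 widest peaks and the 3 densest windows were named by a rule fixed before the data were examined for the case that peaks could not be assigned to genes, and the other regions named were chosen later. The arm, clustering and score-against-width tests were also fixed before the data were examined. The comparisons by score level, of X with autosomal medians and of clustered with isolated peaks were added later.

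Planned tests of promoter proximity, gene features, 13 gene lists and the EcR/Usp motif were not run. They need release 5 annotation or sequence, and the gene table used here is Release 6. Alternatives kept the top 50% or top 25% of arm peaks by score (ties at the limit kept, 1551 and 766 peaks), changed the neighbour distance to 1 or 20 kb, joined peaks first, or changed the arm length.

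The procedures were tested on simulated data. In 20 simulated lists of 3053 scores, the background was recovered with an error of at most 0.00134. Of pileups without a raised local background, 100% were recovered. The scores were made with the Poisson formula that was then fitted. The simulation therefore checks the fitting, not whether the formula or tolerance holds for the deposited scores. At most 7.57% of peaks given a raised local background were placed on the series. In simulated lists of 2970 arm peaks, 20 of 20 with planted clusters and 1 of 20 without were called clustered. With the X density lowered to 70%, 20 of 20 were called, and 0 of 20 without a difference. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.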

Results

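Chromatin from wandering larvae (the third instar) of *Drosophila melanogaster* carrying a GFP-tagged *usp* transgene was immunoprecipitated with a rabbit polyclonal antibody to GFP. The *usp* gene encodes Ultraspiracle, the fly counterpart of the vertebrate retinoid X receptor and the partner of the ecdysone receptor EcR. Wandering larvae have left the food and are about to pupariate, a transition driven by pulses of the steroid 20-hydroxyecdysone. The series held 2 ChIP libraries and 2 input libraries, and the question it addresses is where on the genome the tagged receptor was enriched over input at this stage. The authors' processed data form 1 peak list for the whole series, in FlyBase release 5 coordinates, with a score for each peak. Values per library were not analysed here, so no peak has a replicate mean or spread, and sequencing depth per library is unknown.

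The list held 3053 peaks covering 1458 kb. Of these, 2970 lay on the 6 chromosome arms, 61 on the unplaced scaffold set Uextra, 8 on U, 8 on the heterochromatic scaffolds (Het) and 6 on the mitochondrial genome. Peaks on the arms were narrow, with a median width of 326 bp (interquartile range 248 to 485.5 bp) and a lower limit of 201 bp. A small class was broad: 191 arm peaks, 6.43% of them, were wider than 1 kb and made up 25.8% of the sequence covered by arm peaks. Peaks were not assigned to genes, because the gene table used here is in release 6 coordinates.

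The deposited score behaved as the −log10 of a Poisson p-value, which gave each such peak an enrichment over background. The 52 most repeated score values, each shared by at least 10 peaks, were matched by the Poisson upper tail of whole-number fragment pileups over a background of 43.9, with a mean error of 0.00298 score units. A background fitted on alternate values, 43.9, predicted the 26 values left out with a mean error of 0.00325. Of all peaks, 74.5% (exact 95% interval 72.9 to 76.0%) fell within 0.01 of this series. With any of 89 other backgrounds tried, at most 17.5% did. The share depends on that tolerance: 2 of the repeated values, 8.19 (62 peaks) and 9.77 (80 peaks), missed the series by more than 0.01 but less than 0.015. Within 0.015, 80.1% of peaks lay on it, and at most 23.4% with the other backgrounds. For the 2226 arm peaks on the series, the implied pileup was a median of 2.30 times the background (interquartile range 2.14 to 2.57), and the largest was 5.79 times. The weakest peak on the series had a pileup of 79, or 1.80 times the background. A fold is given below only for peaks on the series, with an exact 95% Poisson interval that covers counting error only.

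**Figure D1:**
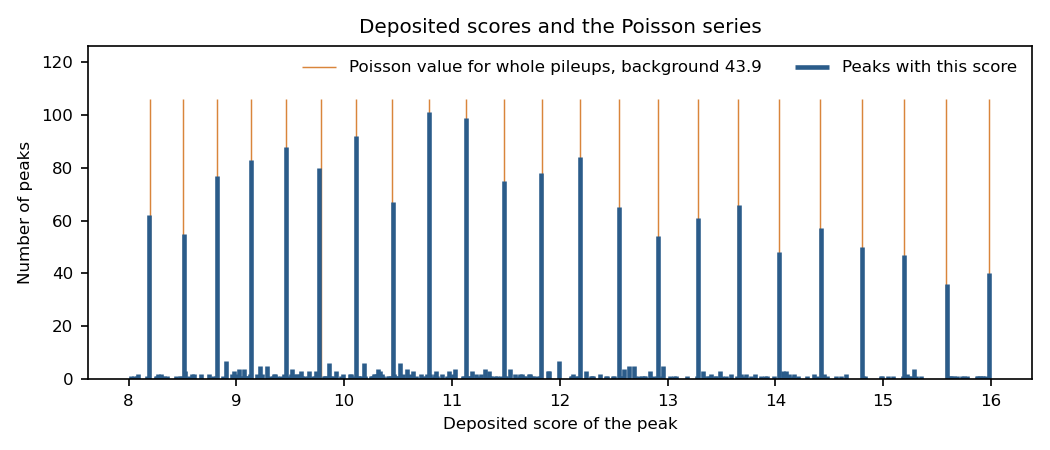
Number of peaks (vertical axis) at each deposited score between 8 and 16 (horizontal axis, blue), with the −log10 Poisson tail of successive whole pileups over a background of 43.9 (orange lines). The tall blue lines sit on the orange ones, and 74.5% of all peaks lie within 0.01 of the series.

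Peak density differed between the chromosome arms. Arm 3L had the most peaks, 814, and the highest density, 33.4 peaks per Mb of the span from its first to its last peak. It was followed by 2R (569 peaks, 28.5 per Mb), 3R (759, 27.4 per Mb) and 2L (578, 25.8 per Mb). The X chromosome had 245 peaks, 11.4 per Mb, which was 0.40 times the density of the autosomal arms together (95% interval 0.35 to 0.46). Arm 4, the dot chromosome, had 5 peaks, 4.42 per Mb.

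By a two-sided exact binomial test against each arm's share of the summed span, adjusted over the 6 arms, X was below its share (8.25% of peaks on 18.3% of the span, adjusted p = 7.3e-54), as was arm 4 (adjusted p = 3.0e-07). In the same exact test, 3L was above it (27.4% of peaks on 20.8% of the span, adjusted p = 5.0e-17), as were 2R (adjusted p = 0.0040) and 3R (adjusted p = 0.022). Arm 2L did not pass (adjusted p = 0.61, exact binomial test). The test takes peaks as independent, which they were not. With peaks less than 5 kb apart joined into regions, X (5.59 regions per Mb), 2R (10.8) and 3L (10.9) kept their calls in the same exact test, while 3R (adjusted p = 0.40) and arm 4 (adjusted p = 0.085, 4 regions, exact binomial test) lost theirs. The density of 2R, 1.15 times that of the other arms, was 1.11 times in the top 50% of peaks by score (adjusted p = 0.15), 1.13 in the top 25% (adjusted p = 0.29) and 1.07 among peaks on the series (adjusted p = 0.25, exact binomial tests). These tests rest on fewer peaks and did not pass, which does not show that the excess was absent.

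The deficit on X was smaller among the strongest peaks. X peaks had a median score of 13.7 against 12.2 on the autosomal arms, a difference of 1.47 (permutation test, two-sided, p = 0.0016, adjusted over 4 comparisons of medians p = 0.0033). The ratio of X to autosomal density was 0.43 among peaks scoring at least 10, 0.52 at 20, 0.64 at 30 and 0.87 at 40. The last ratio rested on 18 X peaks of 110 and had an interval of 0.49 to 1.45. X peaks fell in the top 25% of scores more often than autosomal ones, 33.5% against 25.1% (Fisher's exact test, two-sided, p = 0.0059). The median width on X, 310 bp, did not differ detectably from the autosomal 328 bp (permutation p = 0.21, adjusted p = 0.28). The permutation and Fisher tests of X against autosomal peaks take peaks as independent.

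**Figure D2:**
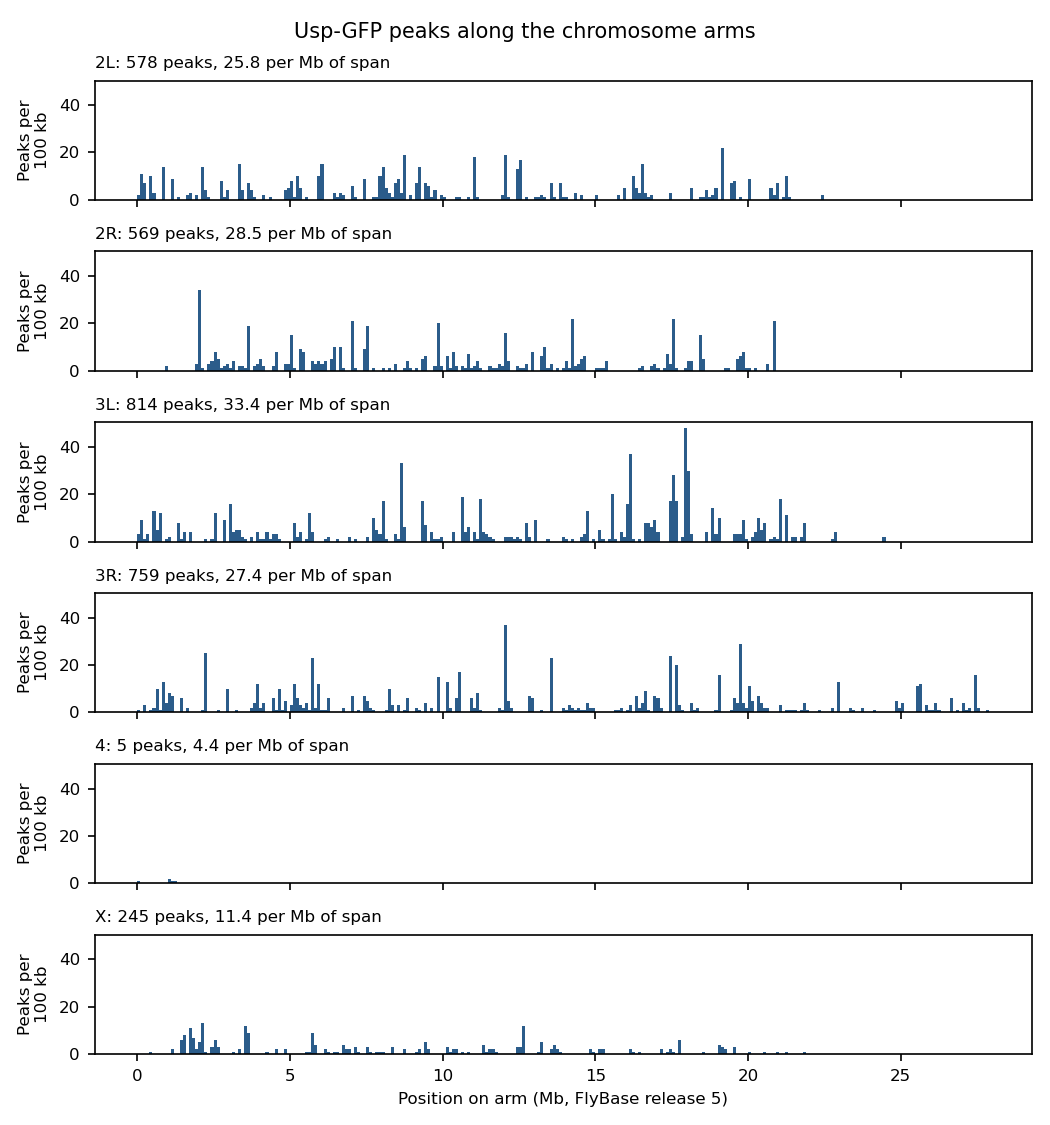
Peaks per 100 kb window (vertical axis) along each chromosome arm (horizontal axis, Mb, FlyBase release 5). Density is highest on 3L, where 1 window reaches 48 peaks, and low on X and 4.

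Peaks were strongly clustered along the arms. Of the 2970 arm peaks, 80.1% had another peak within 5 kb, against a mean of 24.2% and a maximum of 27.5% over 1000 random placements of the same peaks on the same arms (one-sided permutation p = 0.001, the smallest these placements can give). The share was 81.8% on 2L, 80.0% on 2R, 81.8% on 3L, 80.8% on 3R, 69.4% on X and 40% on arm 4, which had 5 peaks. The arms differ in peak density, 11.4 per Mb on X against 33.4 on 3L, and a denser arm gives a higher share by chance. The share expected by chance was not computed per arm, so these shares do not rank the arms by clustering. Joining peaks within 5 kb gave 1065 regions, of which 591 held a single peak and 57 held 10 or more. Those 57 regions contained 883 peaks, 29.7% of all arm peaks. They lay on 3R (18 regions), 3L (16), 2L (13), 2R (7) and X (3).

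Large parts of the arms held no peak. Of 1177 windows of 100 kb, 566 (48.1%) held none, against a mean of 11.2% over the placements. The 92 densest windows, 7.82% of them, held at least 50% of all arm peaks. The longest stretch without a peak was on 3L, from 22872138 to 24457223, a length of 1.59 Mb. It was 1.12 Mb on both 2L and 2R, 0.99 Mb on X, 0.96 Mb on arm 4 and 0.71 Mb on 3R. The stretches on 3L and 2L ended close to the last peak of their arm, at 24463117 and 22430683. The placements allow a peak anywhere in a span, and how much of these stretches reads could map to was not checked.

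**Figure D3:**
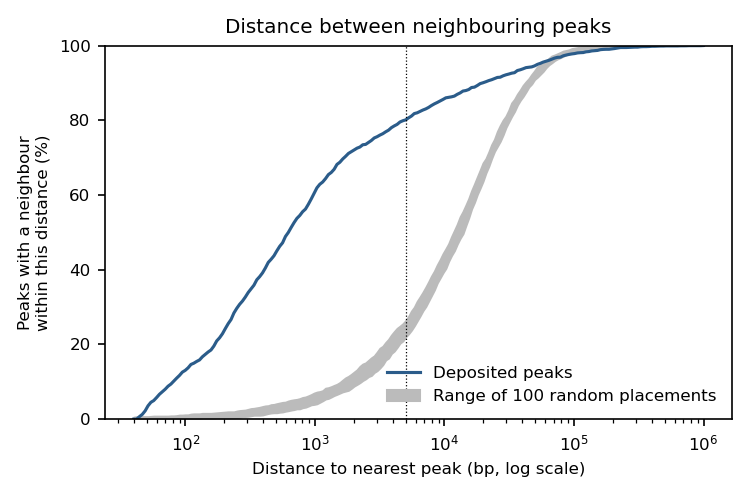
Share of arm peaks (vertical axis, %) with another peak within a given distance (horizontal axis, bp, log scale), for the deposited peaks (blue) and the range of 100 random placements (grey). At 5 kb (dotted line) the deposited peaks reach 80.1%.

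The densest 100 kb window lay on 3L from 17900001 to 18000000 and held 48 peaks covering 61.2 kb. Its strongest peak on the series, from 17955582 to 17964406, was 8825 bp wide and reached 4.33 times the background (3.74 to 4.99). The region joined at 5 kb around it ran over 124 kb, from 17908036 to 18031833, with 71 peaks that covered 68.3% of it, and was the region with most peaks in the list. The second window lay on 3R from 12000001 to 12100000, with 37 peaks covering 19.8 kb. Its strongest peak, 12061763 to 12062190, reached 4.10 times the background (3.52 to 4.75). The third lay on 3L from 16100001 to 16200000, also with 37 peaks, covering 16.3 kb. Its strongest peak, 16188478 to 16188861, reached 3.42 times the background (2.89 to 4.01). No window exceeded 14 peaks in any of the 1000 placements.

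Several other multi-peak regions stood out, and were chosen after their values were seen. On 2R, 35 peaks lay between 1994212 and 2037854. On 3L, 33 peaks lay between 8667807 and 8703846, and 25 between 17557267 and 17587707. On 3R, 25 peaks lay between 2218281 and 2257988. The region with most peaks on X, 2187647 to 2201403, held 13, and that on 2L, 8691451 to 8722781, held 16.

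**Figure D4:**
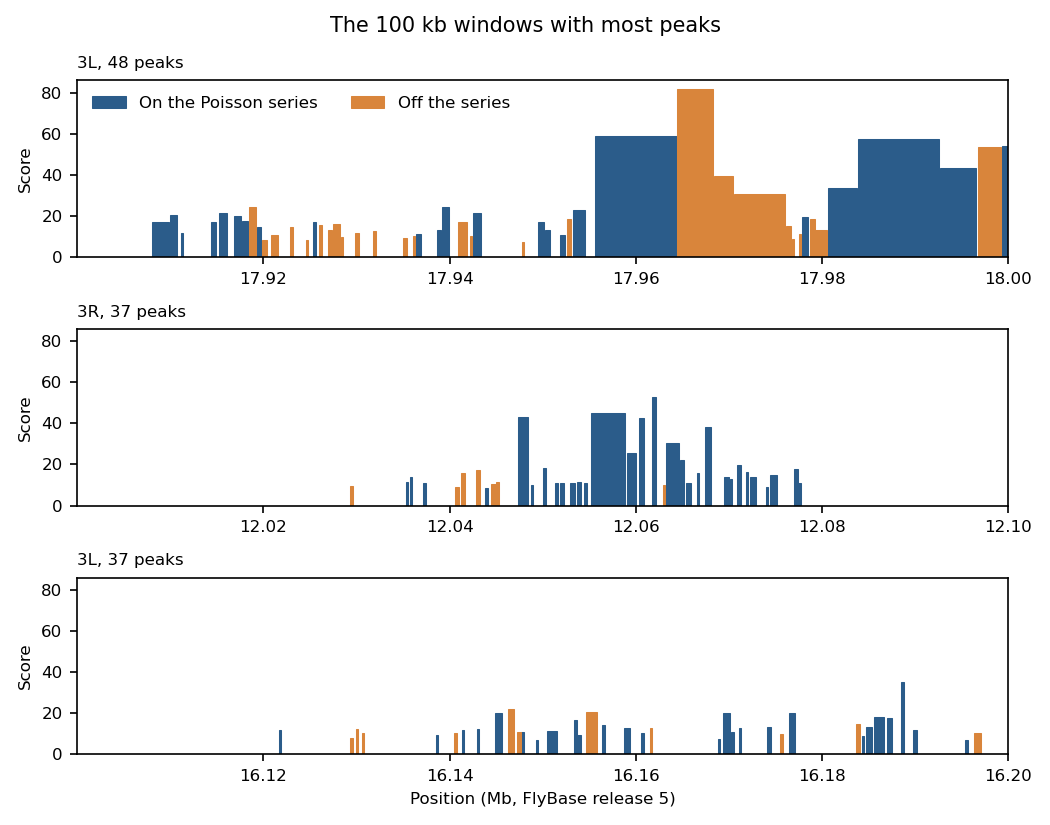
Peaks in the 3 windows of 100 kb with most peaks, drawn to scale (horizontal axis, Mb, FlyBase release 5) with the deposited score as height, blue where the score lies on the Poisson series and orange where it does not. The top window, on 3L, has 61.2 kb covered by peaks and a widest peak of 8825 bp, and in the other 2 the widest peaks are 3654 and 1110 bp.

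The widest peak of the list was on X, from 1834575 to 1848771 (14197 bp), with an implied pileup of 5.33 times the background (4.67 to 6.06). The second was on 3L, from 3239673 to 3249129 (9457 bp, 5.47 times, 4.80 to 6.21). The third, 17955582 to 17964406 on 3L (8825 bp), lay in the densest window. Of the 10 widest arm peaks, 5 lay in regions of 10 or more peaks. Peaks with a neighbour within 5 kb were wider than isolated ones, with medians of 346 and 284 bp (permutation p = 1.0e-05, the smallest the resamples can give, adjusted p = 4.0e-05). Their scores did not differ detectably, with medians of 12.2 and 12.6 (permutation p = 0.37, adjusted p = 0.37). Both permutations took peaks as independent, though the 2379 clustered peaks came from 474 joined regions.

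The highest score in the list, 483, belonged to a 2116 bp peak on X from 10817717 to 10819832. It was 3.11 times the next score on the arms, and its nearest neighbour was 148 kb away. It did not lie on the Poisson series, so no fold is given. The other 9 of the 10 highest scores were all on Uextra. Among these, the peak from 5223903 to 5224552 (score 463) reached 14.1 times the background (13.0 to 15.3) and the peak from 7039330 to 7039840 (score 444) 13.7 times (12.6 to 14.9). The peaks from 27346632 to 27347396 and from 2684382 to 2684953 reached 10.4 (9.48 to 11.4) and 9.87 times (8.96 to 10.8). The remaining 5 were off the series, with scores of 327, 323, 263, 231 and 223.

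After the X peak, the highest scores on the arms were 155 on 3R (8331394 to 8331852), 153 on 3R (2690724 to 2691151), 142 on 2R (942989 to 944229) and 126 on 3R (26213896 to 26214407), all off the series. The strongest arm peak on the series was on X, from 2190128 to 2190630, at 5.79 times the background (5.10 to 6.54), inside the X region with most peaks. It was followed by 2R 3416823 to 3417969 at 5.70 times (5.01 to 6.45) and 2L 480424 to 481255 at 5.58 times (4.90 to 6.33). The intervals of these 3 peaks overlap.

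Higher scores went with wider peaks. Across the 2970 arm peaks, the Spearman correlation between score and width was 0.55 and Pearson's r of their log10 values was 0.55 (permutation p = 1.0e-05 for both, the smallest the resamples can give). The Spearman correlation was lower among strong peaks, 0.37 in the top 50% by score and 0.19 in the top 25% (permutation p = 1.0e-05 for both). Both subsets were cut on score itself, which narrows its range and can lower a correlation. The fall is therefore not read as a property of strong peaks. All of these values are correlations across peaks, which are not independent replicates. Width and score also came from the same peak call, in which a taller enriched stretch can be wider at a given cutoff. The permutations break that link, so their p-values do not show a property of binding. Within arms, the Spearman correlation was 0.59 on 2L, 0.54 on 2R, 0.59 on 3L, 0.56 on 3R and 0.36 on X.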

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

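All tests of the signals below were chosen after the peak list had been seen. Peaks outside the arms are described here because the tests of arms and clustering leave them out, though the ranking by score, the fit of the series and an alternative of score against width used them. Their number was not tested. There were 6 on the mitochondrial genome, 8 on U, 61 on Uextra and 8 on the Het scaffolds.

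The 6 mitochondrial peaks ran from 82 to 14539, had scores of 70.1 to 175, and covered 93.5% of that interval. The 4 on the Poisson series stood at 4.72 to 7.75 times the nuclear background. More mitochondrial DNA in ChIP than in input could give such near-continuous coverage without any binding. The prediction was coverage above that of every arm window of the same length. It was not met, as the highest such window, on 3L from 17955582 to 17970039, reached 98.9%. That bar is the maximum over all arm windows, and how many reach 93.5% was not counted. The coverage therefore does not decide it. By the reading of the series used here, local input at the 4 peaks on it did not exceed the genome-wide background. Discrete sites and extra mitochondrial DNA in ChIP would both allow that, so it does not decide either. The amount of mitochondrial DNA in each library stays open, and no biological explanation was tested.

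The 69 peaks on U and Uextra included 5 adjoining ones on U from 5288477 to 5303070. Along U these 5 were 4778, 4486, 677, 3102 and 805 bp wide. The mitochondrial peaks were, in order, 4706, 1501, 2871, 561, 3096 and 788 bp wide, a similar layout. Whether this part of U carries mitochondrial sequence was not checked, for want of release 5 sequence. If it does, these 5 peaks repeat the mitochondrial signal. They enter the U median and the share on the series below. The median score was 111 on U and 74.6 on Uextra, against 12.2 on the arms. Repeats that are over-represented in ChIP and input alike would raise the local background and take nearly all of these peaks off the genome-wide series. Instead 40 of 69, 58.0% (exact 95% interval 45.5 to 69.8%), lay on it. With other backgrounds at most 17.5% of all peaks did, a share that was not computed for these 69 alone. The 69 as a set thus went against the prediction. The split into those 40 and the rest is by series membership itself, so it is no further test for either part. The other 29, 42.0%, were off the series, and the 58.0% on it was below the 74.9% of arm peaks (Fisher's exact test, two-sided, p = 0.0029), as a raised local background would give, so the explanation stays open for them. The same 58.0% lay within 0.015 of the series. The Fisher test takes peaks as independent, though 5 of the 69 adjoin. Unequal recovery of repeats between ChIP and input, and the placement of multiply mapped reads, were not tested.

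The Het scaffolds had 3 peaks on 2RHet, at 2.23 to 2.87 times the background, and 5 on 3LHet and 3RHet with scores of 26.9 to 128, all off the series.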

How the results depend on the processing

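No paired analysis was possible because the single peak list holds no values per replicate, so no replicate could be left out either. Of 45 alternative values, 33 kept their direction and side of the threshold. The 2L density, 1.02 times that of the other arms, became 0.94 with peaks within 5 kb joined, and passed in neither (exact binomial test, adjusted p = 0.61 and 0.48); no called direction reversed. The median width of 326 bp became 416 bp in the top 50% and 511.5 bp in the top 25% of peaks by score. By the exact binomial test, density over the other arms lost its call on 2R (1.15) in the top 50% (1.11, adjusted p = 0.15), the top 25% (1.13, p = 0.29) and among peaks on the score series (1.07, p = 0.25). On 3R (1.11) the exact test's call was lost in the top 50% (1.03, p = 0.65), the top 25% (1.07, p = 0.49), with peaks within 5 kb joined (1.07, p = 0.40) and on the series (1.08, p = 0.17). Arm 4 (0.17) lost its call with peaks joined (0.39, exact test p = 0.085). The cause was not tested, though each of these settings has fewer items. The low X ratio of 0.40 ranged from 0.40 to 0.57 in these alternatives and passed in each, a permutation of 100 kb windows included (p = 1.0e-05, the smallest it can give), but was 0.87 (0.49 to 1.45) at scores of at least 40. The 3L excess of 1.43 was 1.31 without its region of 71 peaks. Clustering ranged from 1.36 times the placements' mean at 20 kb to 11.3 times at 1 kb. The rank correlation of score with width fell to 0.37 in the top 50% and 0.19 in the top 25%, cuts that narrow the range of score. The share of peaks on the series, 74.5%, was 80.1% with a tolerance of 0.015. Joining at 5 kb for arm densities, length from position 1, series membership and its tolerance, window permutation, the left-out region and the score-width alternatives were added after seeing the data; joining at 1 kb for clustering was planned. Alternatives of promoters, features, gene lists, motifs and arm length without N bases were not run, for want of release 5 sequence. Unknown depth limits all of this to peaks the authors' threshold passed.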

Other observations

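The copy number test and the X values were chosen after the result was seen; the joined-region, centromere, neighbour and local background tests were added after the peak list was seen, with predictions written before their own results, and clustering after joining within 1 kb was planned before the list was examined. Regions of 10 or more peaks made up 3 of 120 joined regions on X (2.5%) and 54 of 945 on the autosomal arms (5.71%), a difference that did not pass (Fisher's exact test, two-sided, p = 0.19). Counted as peaks, 14.3% of X peaks and 31.1% of autosomal peaks lay in such regions (Fisher's exact test, p = 5.7e-09). The count of peaks takes them as independent, which those of 1 region are not. Peaks in such regions had a median width of 377 bp, against 311 bp elsewhere on the arms. Arm 4 held peaks at 87906 to 88213, 1047796 to 1048217, 1051809 to 1052288, 1144163 to 1144524 and 1217718 to 1218054, and those on the series stood at 2.07 to 2.48 times the background.

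Neighbouring peaks had similar strength, though weakly so. Over 1905 pairs of adjacent peaks within 5 kb, the Spearman correlation of their scores was 0.15, above the highest of 10000 permutations of scores within arms, 0.086 (p = 0.0001, the smallest they can give). The fifth of each large arm's span next to the centromere held 197 of 1061 joined regions, 18.6% (exact 95% interval 16.3 to 21.0%), against 20% (exact binomial p = 0.25). The hypothesis of fewer regions there was not borne out at this number of regions. The share was 10.8% on X (13 of 120, exact binomial test adjusted over 5 arms, p = 0.058) and 23.7% on 3R.

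Fewer peaks per Mb on X could come from counting many peaks of few regions, from a lower copy number of X in a sample that holds males, or from fewer sites. Counting is not the whole cause, because the ratio of joined regions was still 0.57 (0.46 to 0.68). It may be part of it, since the ratio of all peaks, each counted individually, was lower, 0.40 (0.35 to 0.46). Lower copy number predicts that local input on X rarely exceeds the genome-wide background, so that X peaks lie on the score series more often. They did, 92.7% against 73.4% of autosomal peaks (Fisher's exact test, p = 1.5e-13, and 98.4% against 79.2% with a tolerance of 0.015). The test takes peaks as independent, though neighbours can share local input. The 245 X peaks joined into 120 regions and the 2725 autosomal peaks into 945, and the shares were not tested by region. The ratio also came nearer to 1 at high scores. What copy number predicts for that was not modelled, and the values had been seen, so it is no test. A candidate explanation is that 1 background for all chromosomes hid weaker X peaks. Fewer Usp sites on X remain open as an untested biological explanation, since the sex of the larvae is labelled unknown.

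The clustering of peaks could come from the caller splitting broad regions, or from chromatin regions over-represented in the DNA. After peaks within 1 kb were joined, 56.3% still had a neighbour within 5 kb, against at most 18.5% over the placements, so splitting at that scale is not the whole cause. Over-representation would take clustered peaks off the genome-wide series, yet 75.9% of clustered peaks lay on it against 71.1% of isolated ones (Fisher's exact test, p = 0.017; 82.1% against 75.6% with a tolerance of 0.015). The test takes peaks as independent. Peaks in regions of 10 or more showed no such excess, with 73.7% on the series against 75.5% of other arm peaks (Fisher's exact test, p = 0.33). In the 3L region of 71 peaks, 52.1% were on it. A raised local background was therefore not found for clustered peaks as a whole, but stays open for the densest regions. Clusters of bound sites around particular genes are a hypothesis that release 5 annotation would test.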
